A study of Homo sapiens with 6 samples.

How the data were processed

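RNA of 6 human fibroblast cultures was hybridised to Agilent whole-genome arrays, 1 array per culture. Airway and distal lung fibroblasts came from the same 3 donors, per the labels' protocols, which call them matched pairs; the labels' donor marks were used only to pair arrays. Each deposited scanner file held spot intensities of 1 channel, written by Agilent Feature Extraction 9.5.3.1 per the file headers. The processed signal used here is an intensity that the authors' scanner software had background-subtracted and detrended, per the file headers, with no scaling between arrays. The mean spot signal and the local background median, also deposited intensities, served an alternative. The labels name the dye Cy5, while the files carry the 1 channel under the software's green prefix; that channel was used, and no comparison of channels was possible.

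The authors' deposited value table holds log2 values. Its columns follow the scanner files' median spot signal (Spearman correlation across spots at least 0.9996 on each array), share a floor of 5.481, and have medians of 7.22, 7.23 and 7.18 for the airway arrays and 7.25, 7.25 and 7.22 for the distal lung arrays. Its scaling method is not given in the sources used here, so it served as an alternative only.

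Values were log2 of the processed signal minus the array's 75th percentile. Control spots and spots with outlier flags were left out and spots of a probe averaged. A probe was tested if well above background on all 3 arrays of at least 1 region, which left 27500 of 41000 probes. For a gene with several probes, the one of highest mean stood for the gene, giving 20229 genes and unnamed transcripts, 13702 of them with a current symbol. Probes were named through the RefSeq gene table by accession (23680 probes), symbol (2802) or synonym (1128); the remaining 13390 kept the file's name. Probe coordinates are those of the files, on hg18. A probe not well above background on any array of a region has only a bound there, given as "at least N-fold": the bright region's mean against the mean, per array, of the higher of the lowest well-above-background signal and the probe's own.

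The comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg), with the donor pair as a fixed block, as the labels describe matched pairs; residual degrees of freedom were 2 and prior degrees of freedom 2.34. Arrays of the same donor deviated together from their group means (r across genes 0.273, 0.422 and 0.494), against -0.409 to 0.0469 for arrays of different donors. Each slide and scan held 1 donor, so a slide block is the donor block. The 49 gene lists were tested with camera (preset correlation 0.01), camera with an estimated correlation, and fry, adjusted over the lists. With the preset correlation, camera takes its degrees of freedom from the number of genes, so its p measures spread over genes, not donors. With an estimated correlation it takes the 2 residual degrees of freedom, so hardly any list could pass. The design, the lists, the rule for named genes and all alternatives except 2 were fixed before the data were examined. Those 2, the intensity trend with no replicate block and the pericyte list without contractile members, and several tests of explanations were chosen after seeing the data. The rule took up to 15 genes per direction past an adjusted p of 0.05 with all pairs on the same side, filled to 10 by smallest p among those with a log2 difference of at least 1; per list up to 4 members per direction past the threshold, or the 2 of smallest p where none passed; and ACTA2, COL1A1, COL3A1, FN1, CCN2, TGFB1, PTGS2 and MKI67. Genes of the Y chromosome and XIST were never reported.

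The steps were tested on simulated data: 5 runs of 20229 genes with the real means, donor effects and distribution of variances, and 200 changed genes. The paired fit recovered 0% of genes changed by 1 on the log2 scale, 18.4% at 2, 66% at 3 and 91.2% at 5, with 4.77% of calls false. With the donor as a random block these were 6.8%, 68%, 88.8% and 96.8%, with 14.9% of calls false, and with no donor term 0%, 14%, 49.6% and 89.2%, with 1.29% false. These rates depend on the share of changed genes, which is not known for the real arrays, so they need not hold there. A simulated list of 25 genes shifted by 1 had an unadjusted camera p under 0.05 in 5 of 5 runs, and an unshifted one in 0 of 5. Residuals were drawn independently for each gene, so the simulated lists held no correlation between members. In the real data the estimated correlation reached 0.226 for cell cycle genes, for example. The runs therefore give no rate of false list calls for the real lists.

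Alternatives changed the donor term, background correction (normexp, offset 50), scaling (quantile, median, the authors' value table), the filter on dim probes, the choice of probe, variance moderation, array weights and the threshold, and left out each donor and each array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.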

Results

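Airway and distal lung fibroblasts, grown out of endo- and transbronchial biopsies of the same people, were compared by gene expression array. The series held 6 arrays, 1 per culture: 3 of airway fibroblasts and 3 of distal lung fibroblasts, forming 3 donor-matched pairs. The cells, at passage 3 per the treatment protocol (the growth protocol allows 1 passage more), were serum-deprived for 24 h and cultured for a further 15 h before RNA was taken. Between 66.2% and 74.1% of the gene spots lay well above background on each array, and no spot was saturated. The number of arrays limits the precision of every value below. Differences are distal lung minus airway on the log2 scale, with the standard error from limma, and n = 3 pairs throughout.

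The comparison asked which transcripts differ between fibroblasts of the 2 lung regions. Among the 20229 genes and unnamed transcripts tested, distal lung fibroblasts carried more mRNA for the muscle protein SYNPO2, for WNT2, WNT5A and the lung mesenchyme factor TBX4, and less for CILP, TLR4 and PTGFR, but no single gene passed the fixed threshold in the paired limma fit. The smallest Benjamini-Hochberg adjusted p was 0.0517, with 274 genes under 0.10, 181 of them higher and 93 lower in distal lung fibroblasts, and 2889 at an unadjusted p under 0.05. The count under 0.10 was 208 without donor pair 1 and 0 without donor pair 2, without donor pair 3, with normexp background correction and with no filter on dim probes. Normexp left 847 at an unadjusted p under 0.05, fewer than that threshold alone would give among 20229 genes if no gene differed. Of the 1965 genes at least 2-fold apart, 1597 had all 3 pairs on the same side, 1014 higher and 583 lower. Selection by a large mean difference favours pairs on the same side, so that share is no separate support. Over all genes 39.2% had 3 pairs on the same side, against 25% by chance. The count depended on how the donor was modelled: 34 genes passed with no donor term, 29 higher and 5 lower, and 464 passed with the donor as a random block, 288 higher and 176 lower. All 34 of the former lay among the 274 with a paired adjusted p under 0.10. Each slide carried the arrays of 1 donor, so the donor term also took up the slide. All airway arrays lay in position 3 and all distal lung arrays in position 1 of their slide, so region and position could not be separated.

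The genes of smallest p within each direction, among those at least 2-fold apart with all pairs on the same side, are given as values that did not pass. SLC24A3, a sodium, calcium and potassium exchanger, was at least 42.8-fold higher in distal lung fibroblasts, and PPP1R14A, an inhibitor of myosin phosphatase, at least 89.7-fold, because neither was well above background on any airway array (adjusted p = 0.0517 for both). WNT2, a secreted ligand of the developing lung mesenchyme, was likewise at least 21.5-fold higher, SYNDIG1 at least 10.7-fold and the calcium-activated scramblase ANO5 at least 5.42-fold (adjusted p = 0.0517). Of the genes measured in both regions, SYNPO2, an actin-bundling protein of muscle, differed by 6.35 ± 0.37 and ARHGDIB by 5.92 ± 0.34 (adjusted p = 0.0517). The ligand WNT5A was 8.58-fold higher, the protease inhibitor SERPINB2 by 3.51 ± 0.21 and the tight junction protein CLDN1, above background on 1 of 3 airway arrays, by 4.91 ± 0.24 (adjusted p = 0.0517). The WNT5A probe lies at chromosome 3: 55476693-55476752 and the WNT2 probe at chromosome 7: 116704621-116704680 (hg18).

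Lower in distal lung fibroblasts were TLR4, the endotoxin receptor (-4.20 ± 0.24), RGS16, a regulator of G protein signalling (-3.94 ± 0.24), the slow skeletal troponin TNNT1 (-3.38 ± 0.17) and the glycosyltransferase GCNT1 (-2.52 ± 0.16), each with an adjusted p of 0.0517 and 0 of 3 pairs above 0. CILP, a cartilage matrix protein, was not well above background on any distal lung array and was at least 21.6-fold higher in airway fibroblasts (adjusted p = 0.0517). The homeobox gene HOXC9 was at least 2.77-fold higher in airway fibroblasts (adjusted p = 0.0517), but its dim signal gave 0.10 in the opposite direction after normexp background correction. With that correction the smallest adjusted limma p of any gene was 0.341, so no gene named here was near the threshold. COLEC12, a scavenger receptor, differed by -3.07 ± 0.26 (adjusted p = 0.0662), the matrix protein ECM2 by -2.46 ± 0.19 (0.0604), the antiviral enzyme OAS1 by -2.10 ± 0.17 (0.0629) and the prostaglandin F receptor PTGFR by -2.08 ± 0.17 (0.0662). With the donor as a random block, 55 of the 109 named genes passed an adjusted p of 0.05, and with no donor term 12 did. Over all 20229 genes 464 and 34 passed. Most named genes were chosen by smallest p in these same arrays, so their passing is no separate support. In the simulation 14.9% of the random block's calls were false.

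**Figure D1:**
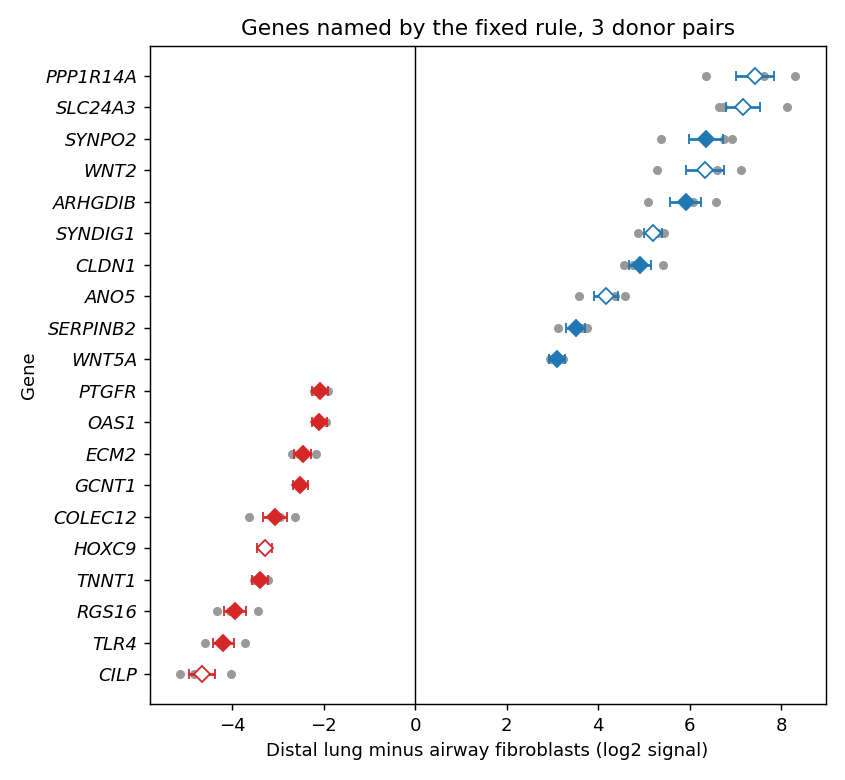
Distal lung minus airway difference in log2 signal (x axis) for 20 genes (y axis). These had the smallest p within each direction, ranked separately, among genes at least 2-fold apart with all 3 pairs on the same side. Diamonds with bars are the mean and standard error, grey points the 3 donor pairs, and open diamonds mark genes not well above background on any array of a region; no pair crosses 0 here, although HOXC9 changes sign after normexp background correction, and no gene passed the adjusted threshold.

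Genes of the contractile apparatus were higher in distal lung fibroblasts as a group. Of 26 measured members of the contractile and myofibroblast list, 13 rose and 1 fell when adjusted over the list alone, and 0 when adjusted over all genes. The mean shift against all genes was 1.69 (limma camera, adjusted p = 7.89e-10; adjusted p = 0.727 with an estimated correlation). The camera p, here and for the lists below, measures spread over genes and not over the 3 donors. The p with an estimated correlation rests on 2 residual degrees of freedom. The shift was 1.53 to 1.87 within single pairs and 1.09 with normexp background correction. Besides SYNPO2, LMOD1, an actin nucleator of smooth muscle, differed by 2.41 ± 0.17. Among members outside the naming rule, chosen after their values were seen, the smooth muscle actin ACTG2 differed by 7.53 ± 1.0, the smooth muscle myosin MYH11 by 6.18 ± 0.78, and calponin CNN1 by 4.12 ± 0.53, each higher in 3 of 3 pairs. Transgelin, TAGLN, differed by 3.13 ± 0.35. ACTA2, the actin used as a myofibroblast marker, differed by 0.89 ± 0.26 (adjusted p = 0.272 over all genes), and the collagen receptor subunit ITGA11 by -2.62 ± 0.57.

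Markers of pericytes and vascular smooth muscle moved with the contractile genes: 7 of 13 measured members rose and 0 fell when adjusted over the list alone, with a mean shift of 2.76 (camera adjusted p = 2.74e-05; adjusted p = 0.727 with an estimated correlation). That shift was 1.46 with normexp background correction and 1.82 with no filter on dim probes. Desmin, DES, differed by 3.31 ± 0.33, whereas RGS5 differed by 0.20 and PDGFRB by -0.65. ABCC9 differed by 3.28 and KCNJ8 by 2.52, each higher in 3 of 3 pairs (adjusted p = 0.366 and 0.51 over all genes). RGS5, PDGFRB, ABCC9 and KCNJ8 were chosen after their values were seen. Without the members shared with the contractile list, 7 markers remained and the shift of 1.29 was not called (adjusted p = 0.395). Of 19 targets of YAP and SRF, transcriptional regulators that respond to tension and actin, 6 rose and 0 fell when adjusted over the list alone (mean shift 1.18, camera adjusted p = 7.63e-06; adjusted p = 0.783 with an estimated correlation). The shift was 0.79 with normexp background correction, and the call was kept without the contractile members (0.97, adjusted p = 0.00139). Tissue factor, F3, was at least 40.8-fold higher in distal lung fibroblasts, not being well above background on any airway array, and CCN2 differed by 0.97 ± 0.45. The TGF-beta target list showed no shift (0.06, camera adjusted p = 0.466), with 3 of 28 members risen and 3 fallen when adjusted over the list alone. Among these, the NADPH oxidase NOX4 differed by 1.39 ± 0.21, and TGFB1 itself by -0.50 ± 0.22 (adjusted p = 0.4).

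Metallothioneins, small metal-binding proteins, were higher in distal lung fibroblasts: 8 of 9 measured members rose and 0 fell when adjusted over the list alone, and 0 over all genes (mean shift 1.04, camera adjusted p = 2.91e-07; adjusted p = 0.727 with an estimated correlation). MT1E differed by 1.38 ± 0.18 and MT1G by 1.11 ± 0.17. These genes are near-identical in sequence, so their probes are not independent measurements. Of 35 cell cycle genes, 8 rose and 0 fell when adjusted over the list alone (mean shift 0.45, camera adjusted p = 5.9e-04; adjusted p = 0.783 with an estimated correlation). TOP2A, a DNA topoisomerase of dividing cells, differed by 1.91 ± 0.31 and the spindle checkpoint kinase BUB1 by 1.16 ± 0.20. The list call ended with normexp background correction (shift 0.16, adjusted p = 0.0745; range over the alternatives 5.01e-06 to 0.783). The shift was 0.28 without donor pair 2. The proliferation marker MKI67 was not tested, since its probe did not pass the filter on dim probes, so its direction is not known here. 

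Proteoglycan genes were lower on average in distal lung fibroblasts. Of 25 measured members 6 fell and 1 rose when adjusted over the list alone. The mean shift was -1.0 (camera adjusted p = 0.0206, or 0.783 with an estimated correlation). The median difference was -0.30 against a mean difference of -0.93, so a few large differences weighed heavily. Aggrecan, ACAN, the main cartilage proteoglycan, differed by -4.91 ± 0.45 and osteomodulin, OMD, above background on 1 of 3 distal lung arrays, by -2.81 ± 0.26 (adjusted p = 0.0662 for both). The call ended in 9 of 18 alternatives, among them quantile normalization (shift -0.99, adjusted p = 0.065; range over the alternatives 8.42e-04 to 0.783), without donor pair 1 (shift -0.77, adjusted p = 0.052) and without donor pair 3 (shift -1.09, adjusted p = 0.0653). No shift was called for fibrillar collagens and their processing enzymes (-0.14, adjusted p = 0.641), with 0 of 27 members past the threshold even adjusted over the list alone. That shift turned to 0.11 without donor pair 3. COL1A1 differed by -0.02 ± 0.61 and COL3A1 by -0.64 ± 0.74, which became 0.72 and 0.13 without donor pair 3, and fibronectin, FN1, by -0.33 ± 0.17. Elastic fibre genes were not called as a group (adjusted p = 0.203), with 1 of 19 risen and 3 fallen when adjusted over the list alone, the microfibril protein MFAP5, above background on 1 of 3 distal lung arrays, by -6.53 ± 0.95 and fibulin-1, FBLN1, by -1.40 ± 0.19. Of 26 other matrix glycoproteins 4 rose and 3 fell when adjusted over the list alone (adjusted p = 0.441), with spondin SPON1 at 3.55 ± 0.26. Of 19 basement membrane genes 4 rose and 2 fell in the same sense (adjusted p = 0.419), with a median of -0.03 and a mean shift of 0.62 that differ in sign. The collagen chain COL4A6, above background on 1 of 3 airway arrays, differed by 6.65 ± 1.24.

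Markers fixed for alveolar fibroblasts were higher in distal lung fibroblasts: 4 of 17 rose and 1 fell when adjusted over the list alone (mean shift 0.93, camera adjusted p = 0.0422; adjusted p = 0.783 with an estimated correlation). The call ended in 6 of 18 alternatives, among them normexp background correction (shift 0.47, adjusted p = 0.0678), no filter on dim probes (shift 0.52, adjusted p = 0.122) and without donor pair 1 (shift 0.66, adjusted p = 0.141), with a range of 8.64e-04 to 0.783. WNT2 led this list, and the membrane protein GPM6B went the other way (-3.23 ± 0.39). Markers fixed for adventitial and airway fibroblasts went both ways, with 3 of 18 higher and 4 lower in distal lung fibroblasts when adjusted over the list alone (mean shift -1.01, adjusted p = 0.203). Collagen COL14A1 was lower (-2.05 ± 0.18) and cadherin CDH4 5.66-fold higher. Among 39 patterning transcription factors 5 rose and 2 fell when adjusted over the list alone (adjusted p = 0.416). TBX4, a T-box factor of lung mesenchyme, differed by 5.87 ± 0.68, above background on 1 of 3 airway arrays and on 3 of 3 distal lung arrays, and PRRX1, a mesenchymal homeobox factor, by -1.53 ± 0.19. Of 15 HOX genes measured, HOXB5 rose (1.19 ± 0.20) and HOXC9 fell when adjusted over the list alone.

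The lists of signalling genes were not called by camera. In the BMP and activin list (27 measured) and the retinoid list (15 measured) 0 members passed when adjusted over the list alone, while members of the following lists did. In the WNT list 5 of 32 rose and 3 fell (adjusted p = 0.299 for the list), and among 38 growth factors and receptors 5 rose and 0 fell (adjusted p = 0.0917). FGF9 was at least 42.2-fold higher in distal lung fibroblasts, without signal well above background on any airway array, and ANGPT1, an angiopoietin, differed by 2.18 ± 0.28. Both insulin-like growth factor binding proteins that passed over their list of 6 rose, IGFBP2 by 3.08 ± 0.28 and IGFBP5 by 3.22 ± 0.43. Among chemokines 1 of 11 rose, CCL2 (2.82 ± 0.20), and among 26 cytokines and NF-kB targets 3 rose and 1 fell, with IL6 at 2.22 ± 0.29 and LIF at 1.64 ± 0.19. Of 18 prostanoid pathway genes 2 rose and 3 fell; thromboxane synthase, TBXAS1, differed by 2.13 ± 0.21, and PTGS2, the inducible cyclooxygenase, by -1.38 ± 0.62, which normexp background correction turned to 0.20. In the hedgehog list of 8 genes 1 rose and 4 fell, with the co-receptors GAS1 at -1.56 ± 0.23 and BOC at -1.30 ± 0.25. Tested for change in either direction by fry, 39 of the 49 lists had an adjusted p under 0.05. That test is against no change, not against other genes. As 2889 of the 20229 genes had an unadjusted limma p under 0.05, the count does not set these lists apart.

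Markers of other cell types gave no call by camera apart from the pericyte and smooth muscle list. Of 20 epithelial markers 0 passed when adjusted over the list alone (mean shift 0.43, adjusted p = 0.31), with EPCAM, above background on 1 of 3 airway arrays, at 3.55 ± 1.22 and KRT18 at -0.94 ± 0.23. Of 9 endothelial markers 0 passed (adjusted p = 0.391). Of 8 haematopoietic markers KIT rose (1.61 ± 0.26, but -0.06 without airway replicate 2 and no donor term; adjusted p = 0.532 for the list), of 8 mesothelial markers 2 rose and 1 fell (adjusted p = 0.557), and of 14 chondrocyte markers 1 rose and 2 fell (mean shift -0.98, adjusted p = 0.216). Skeletal muscle markers shifted by -0.29 against all genes (camera adjusted p = 0.171), with TNNT1 lower and desmin higher. Against no change, without a comparison with other genes, fry called 3 lists: contractile genes (adjusted p = 0.0126), metallothioneins (0.0494) and skeletal muscle markers (0.0177). None of the 18 RNA quality and housekeeping genes passed (mean shift -0.08, turning to 0.03 without donor pair 3; adjusted p = 0.754).

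**Figure D2:**
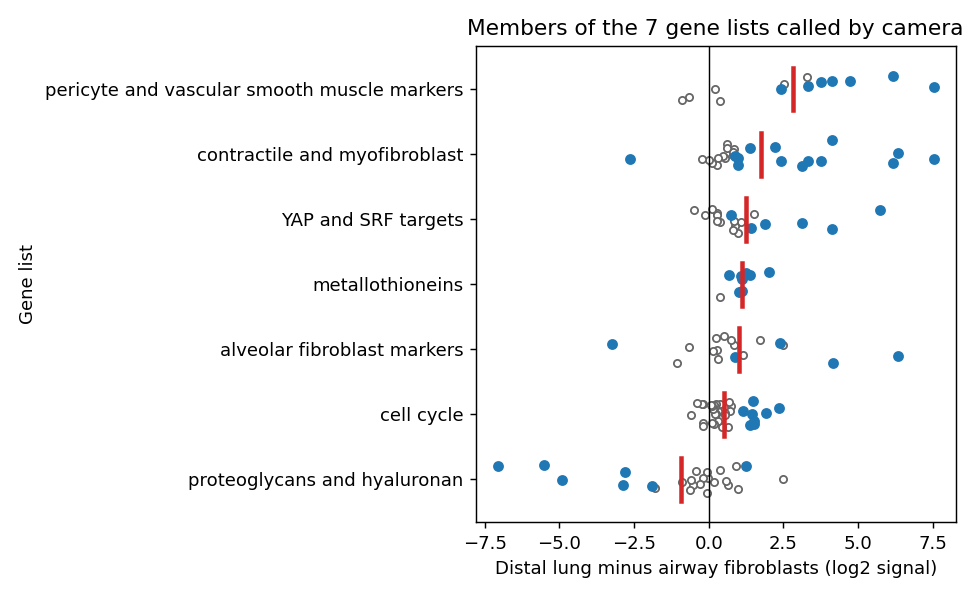
Distal lung minus airway difference in log2 signal (x axis) of each measured member of the 7 gene lists called by camera (y axis). Filled points passed when adjusted over their list alone, open points did not, and vertical bars are list means. The contractile list holds 13 filled points above 0 and 1 below. None of the calls was kept with an estimated correlation, a test with only 2 degrees of freedom.

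With the regions exchanged within 1 donor pair, splits that keep the pairing called 11, 0 and 8 lists, against 7 for the real regions.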

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

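The moderation with an intensity trend and no replicate block, and the pericyte list without contractile members, were chosen after seeing the data. The paired count of 0 genes stayed 0 without each donor pair in turn (0 to 0), with normexp, quantile or median scaling, with no filter on dim probes, and with a 2-fold minimum. It became 34 genes (29 higher and 5 lower in distal lung fibroblasts) with no replicate block, 464 (288 and 176) with a random replicate block, 14 (12 and 2) in the authors' value table, 8 (4 and 4) among probes above background on all 6 arrays, 10 (7 and 3) with the mean of a gene's probes, and 46 (37 and 9) with every probe tested. It became 34 (21 and 13) with an intensity trend and robust moderation, 28 (23 and 5) with that and no replicate block, 67 (47 and 20) with array weights, and 274 (181 and 93) at an adjusted p under 0.10, a count that was 0 without replicate 2, without replicate 3, with normexp and with no filter. In the simulation the random block gave more false calls than its nominal rate. The cause of the other moves was not tested.

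With no replicate block and 1 array left out, the count ran from 0 to 103 genes, 0 to 82 higher and 0 to 21 lower: 29 without airway replicate 1, 1 without airway replicate 2, 103 without airway replicate 3, 1 without distal lung replicate 1 and 0 without either of the other distal lung replicates. The median of all differences, 0.03, was 0.12 with normexp. Differences of at least 2-fold kept their sign in 94.2% of genes or more in every setting. The settings share arrays, and some change only the test and not the differences, so this is no independent check. Of the 109 named genes 6 changed sign in some setting, 1 of them (HOXC9, normexp) among the 20 chosen by smallest p within each direction.

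Of the 7 list calls 0 were kept with an estimated correlation. By fry, which tests against no change and not against other genes, 3 lists were called, 1 of them (skeletal muscle markers) outside the 7. Camera called 7 to 11 lists without 1 donor pair, the 11 without pair 3, and 6 to 15 without 1 array and no replicate block, the 15 without airway replicate 3. All other settings gave 5 to 8, 8 with no replicate block. Apart from fry and the moderation settings, which camera does not use, contractile genes and metallothioneins were called in 17 of 18 alternatives each, YAP and SRF targets in 18 of 19, pericyte markers in 17 of 19, cell cycle genes in 16, alveolar markers in 12 and proteoglycans in 9 of 18. Slide as a block and another channel were not run, since slide equals donor and the files hold 1 channel. Genes not well above background in a region have only bounds there.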

Other observations

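The tests of scaling, of smooth muscle cells, of a TGF-beta response and of neighbouring genes were chosen after the result was seen, the last on noticing 4 adjacent genes. Outside the fixed lists, and named after their values were seen, the oxytocin receptor OXTR (4.92 ± 0.46, adjusted p = 0.068) and the flavin monooxygenase FMO2, above background on 1 of 3 airway arrays (5.72 ± 0.63, adjusted p = 0.0765) were higher in distal lung fibroblasts in 3 of 3 pairs. Of the listed proteoglycans, OGN, likewise named after its value was seen, was lower (-5.51 ± 0.70, adjusted p = 0.0912). The median SD of a gene was 0.41 among airway and 0.30 among distal lung arrays, and 65.1% of genes had the larger SD in airway fibroblasts. Without replicate 3 these were 0.24, 0.21 and 54.6%; airway replicate 3 had the lowest share of spots above background (66.2%) and the highest variation between replicate spots (14.3%).

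Several of these genes are neighbours. OGN, OMD, ASPN and ECM2 lie side by side on chromosome 9 (OGN probe at 94186201-94186260, ECM2 probe at 94298035-94298094, hg18) and all were lower in distal lung fibroblasts in 3 of 3 pairs, with ASPN at -2.88 ± 0.38. IGFBP2 and IGFBP5 on chromosome 2, and ADAMTS8 and ADAMTS15 on chromosome 11, were each higher as a pair. A candidate explanation, that neighbouring genes share the direction of the regional difference, was tested on 10360 adjacent gene pairs within 200 kb. In 102 of them both genes were at least 2-fold apart in the same direction, against a mean of 56.2 and a highest of 88 over 10000 shuffles of the differences (permutation p = 1e-04, the smallest the shuffles can give), and in 33 in opposite directions (mean 50.9). Signal shared between related probes may account for part or all of this: without pairs whose symbols share their first 3 letters the count was 68, against a mean of 52.4 (permutation p = 0.0168), but that leaves in relatives of unlike names. Without the pairs of the 4 genes on chromosome 9 the count was 99, against a mean of 56.2 (permutation p = 1e-04, again the smallest possible). Without these and without pairs that share a first letter or their last 2 characters it was 56, against a mean of 48.3 (permutation p = 0.141). Family signal and shared regulation of neighbours both stay open.

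For the higher contractile genes in distal lung fibroblasts, slide position could not be separated from region. An offset common to all genes cancels in the list's shift, so it could not be tested this way. The spike-ins and the alternative scalings below bear only on offsets that vary with signal. They argue against these within the signal range of the spike-ins well above background. Offsets at dimmer signal and other effects of slide position stay open. Of 7 spike-in RNAs well above background, meant to be added in equal amounts, the one that differed most did so by -0.14 (log2), and no single pair by over 0.33, against a shift of 1.69 for the list. Among the dimmer spike-ins, E1A_r60_a107 differed by -0.28, with a lowest pair of -1.06, while E1A_r60_3 differed by 0.04 and E1A_r60_a104 by -0.06. The list's shift was at least 1.09 with normexp, quantile normalization and the value table, and called in each. Smooth muscle cells or pericytes carried into the distal cultures stay open. Markers of these cells outside the contractile list shifted by 1.29, 0.71 to 2.28 within pairs, uncalled. Among such markers, MCAM differed by 4.74 ± 0.74, ABCC9 by 3.28 and KCNJ8 by 2.52, but RGS5 by 0.20 and PDGFRB by -0.65. A TGF-beta response is not decided either, since targets outside the contractile list averaged -0.087, from -0.40 to 0.13 within pairs. A difference between the fibroblasts of the 2 regions, which the design names, also stays open and was not tested apart from these.

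The other splits that part all 3 pairs number 4 with the real one, too few for a share under 0.05. At an adjusted p of 0.05 the paired count was 0 for the real split and 0 as the highest of the others, so 4 of 4 reached it. At 0.10 it was 274 against 0, though also 0 for the real regions without replicate 2 or without replicate 3, with the random block 464 against 0, and with no block 34 against 0, so in each case 1 of 4 reached the real count. Of the list calls, 3 of 4 splits gave as many as the real 7, the highest 11 with the regions of 1 pair exchanged.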
